A study of Homo sapiens with 14 samples.

How the data were processed

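Poly(A) RNA of HT-29 cells was made into dUTP stranded libraries and sequenced as paired ends on an Illumina NovaSeq, per the labels' protocols. The deposited table holds whole-number counts per gene for 36555 gene IDs and 14 libraries, beside 14 columns of FPKM that were not used. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2 were among the tools of the study, with no role or order given. The genome build, the annotation, the program that counted reads and its strand setting are not given in the sources used here. Of the gene IDs, 35518 are in GENCODE v29, 28114 with the same start and 22018 with the same start and end. Positions are printed as the deposited table gives them. Because the strand setting is not known, values of overlapping and antisense genes are uncertain, as are those of close paralogs and readthrough transcripts.

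Groups came from the sample labels: 3 control, 2 ferrostatin-1, 2 liproxstatin-1, 2 TNF, 3 TNF with ferrostatin-1 and 2 TNF with liproxstatin-1. The design speaks of 3 technical replicates per group, and why 4 groups hold 2 is not known. Because the replicates are labelled technical, no biological replication is known to enter the tests. Within groups, no pair of libraries was alike within sampling noise (chi-square of at least 16.1 per degree of freedom), so none was treated as 1 library deposited 2 times. Library numbers in the text are those of the count columns. The columns of ferrostatin-1, liproxstatin-1 and TNF are numbered 1 and 3 where the titles say 1 and 2, so these libraries were matched to titles by group only. The 10 most counted genes took 5.40% to 6.76% of the counts of a library, and mitochondrial genes 4.48% to 6.06%. Even numbers made up 56.35% to 58.7% of counts from 1 to 8. Whether both mates of a pair were counted is not given in the sources used here, so 1 count is not known to be 1 fragment.

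Deposited counts were scaled by the trimmed mean of M values (TMM factors 0.947 to 1.05) in edgeR 4.0.16 under R 4.3.3, and genes with low counts were removed by filterByExpr, which left 22179 genes. Each of 12 comparisons was tested with edgeR's quasi-likelihood test in a single model of all 6 groups, which share their estimate of the spread, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were TNF against control, each compound against control, each compound with TNF against TNF, the compounds against each other without and with TNF, TNF within each compound, and 3 interactions. Values of log2 fold change carry a standard error taken as their size divided by the square root of the test's F value. Intervals are symmetric 95% t intervals built on it. Both are approximate, most of all for genes near 0 counts in a group. Normalized CPM is given as mean ± SD over libraries. For a gene with 0 counts in all libraries of a group no fold is given, and medians over lists were also computed with such groups set to 3 counts over the group.

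Gene lists (42) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, over the 504 tests of all comparisons. The lists, groups, tests, comparisons and the rule for named genes were set before the data were examined. For the first 7 comparisons that rule took up to 10 rises and 10 falls among called genes that changed at least 2-fold with no overlap between groups and a mean count of at least 50, up to 4 called members per list, and a fixed set of ferroptosis, apoptosis and lipid genes. For TNF within each compound it took genes named for TNF alone, and for the interactions the 10 smallest p-values and list members. The text prints part of the genes so chosen, and KRT81, KRT7 and the other 7 genes that separated libraries were chosen after their values were seen.

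The model was tested on simulated counts with 200 changed genes. For TNF against control it recovered 54.5% of genes changed 4-fold, 29.9% of those changed 2-fold and 2.99% of those changed 1.5-fold, with 4 false calls among 21404 genes. For liproxstatin-1 against control it recovered 66.7% and 41.8% at 4-fold and 2-fold. At 2-fold recovery was lowest for the 3 interactions (5.97%, 7.46% and 8.96%), against 23.9% to 41.8% in the other comparisons, and at 1.5-fold it was 0% to 7.46% over all 12. Apart from the changed genes, each gene had 1 mean and 1 spread over all simulated libraries. The wider gap between the real TNF libraries (chi-square of 226 per degree of freedom, against 16.1 to 82.48 within other groups) was not simulated. These shares and false calls may thus not hold for comparisons with the TNF group. Agreement between comparisons with common libraries was set against 20 simulations of unchanged groups drawn in the same way. Alternatives were relative log expression scaling, no filter, a stricter filter (CPM of at least 1 in 3 libraries), DESeq2 1.42.0, a model of the compared groups alone, the 2-fold threshold and each library left out. Added after the data were seen were a replicate block, a covariate from the 9 genes that separated libraries, an offset for transcript length and GC content, and limma voom with quality weights.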

Results

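RNA was sequenced from HT-29 cells, a human colorectal carcinoma line. Cells were kept in 0.1% DMSO (control) or received 20 uM ferrostatin-1, 20 uM liproxstatin-1, TNF (100 ug/ml as labelled) or TNF with either compound, and treatment lasted 72 h. Ferrostatin-1 and liproxstatin-1 are radical-trapping antioxidants that block lipid peroxidation and ferroptosis, an iron-dependent form of cell death. Ferrostatin-1 is an ethyl benzoate carrying amino and cyclohexylamino groups, whereas liproxstatin-1 is a spiro-quinoxaline amine carrying a chlorobenzyl group. The study asked why these inhibitors act differently on apoptosis caused by TNF, and tested each compound alone to see its effect on unstimulated cells. The analysis used 14 libraries: 3 control, 2 ferrostatin-1, 2 liproxstatin-1, 2 TNF, 3 TNF with ferrostatin-1 and 2 TNF with liproxstatin-1. The design speaks of 3 technical replicates per group, and why 4 groups hold 2 is not known. Since the replicates are labelled technical, p-values are taken to measure only the spread between these samples. Total counts per library ran from 59913850 to 75838597, and 22179 genes were tested.

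The first principal component of log2 CPM held 23.7% of the variance and separated libraries with TNF (41.2 to 62.4) from those without it. The TNF libraries differed more from each other (r = 0.987 across genes) than any other pair of 1 group (r = 0.995 to 0.997). TNF library 1 lay at 121 on the second component and TNF library 3 at 19.7, with the other libraries between -37.8 and 10.2. A set of 9 genes was high in all control and TNF libraries, low in all 3 libraries with TNF and ferrostatin-1, and unequal within the other groups: KRT81, a hair keratin, stood at 47.6 to 48.4 CPM in the controls, 43.7 and 50.4 in TNF, 57.05 in ferrostatin-1 library 1 and 1.45 in ferrostatin-1 library 3. KRT81 reached 1.05 and 14 CPM in the liproxstatin-1 libraries, 1.47 to 1.80 with TNF and ferrostatin-1, and 13.55 and 1.85 with TNF and liproxstatin-1. KRT7, another keratin, had 88.4 and 106.5 CPM in TNF against 11.6 to 14.95 with TNF and ferrostatin-1. These 9 genes were chosen after their values were seen, and CXCL5, SERPINB2 and INHBA among them also belong to gene lists that were tested.

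**Figure D1:**
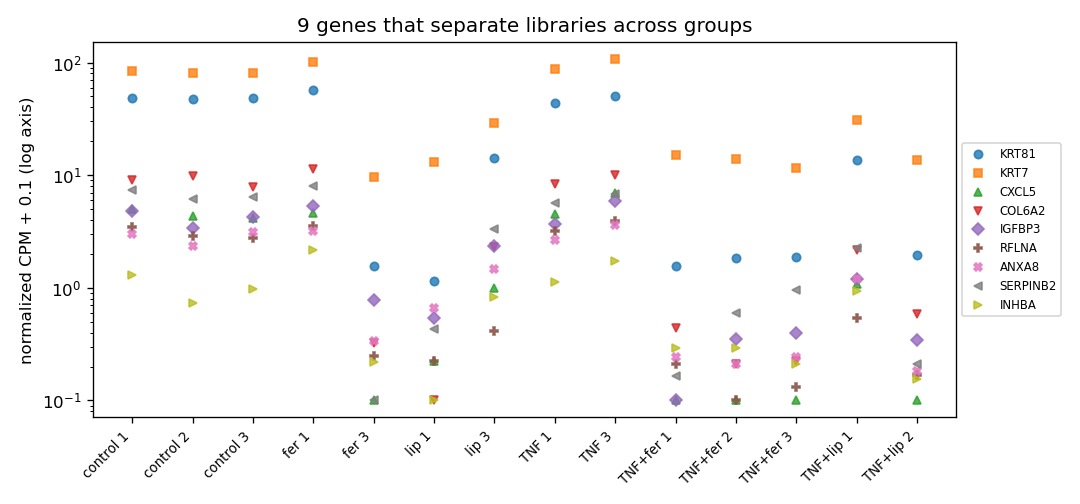
Levels of 9 genes in each of the 14 libraries, as normalized CPM plus 0.1 on a log axis, with 1 symbol per gene. KRT81 lies between 43.7 and 57.05 CPM in the control and TNF libraries and ferrostatin-1 library 1, and between 1.05 and 14 CPM in the others.

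TNF was compared with control to see what TNF did without either inhibitor, and it raised inflammatory, interferon and antigen presentation genes. TNFAIP3, an NF-kB feedback inhibitor (ENSG00000118503, chromosome 6, 137867214 to 137883312, plus strand), rose from 5.80 ± 0.0404 CPM (SD, n = 3) to 105 ± 14.2 CPM (SD, n = 2), a log2 change of 4.18 ± 0.12 (SE, adjusted p = 8.2e-09). The chemokine CXCL8 rose by 4.28 ± 0.14 and the adhesion molecule ICAM1 by 3.24 ± 0.11 on the log2 scale. Of 49 tested NF-kB targets 34 rose, 0 fell and 15 were not called (36 rose adjusted over the list alone). Of 52 interferon-stimulated genes 42 rose and 10 were not called (44 adjusted over the list alone), among them TRIM22 at 3.93 ± 0.19, GBP4 at 3.32 ± 0.17 and CXCL10 at 3.80 ± 0.25. In MHC class I presentation 18 of 20 genes rose (18 adjusted over the list alone), with HLA-B at 4.01 ± 0.17, the peptide transporter TAP1 at 2.61 ± 0.15 and B2M at 2.07 ± 0.13. These 3 lists were called by camera (adjusted p = 2.4e-86, 6.9e-60 and 1.4e-58) and stayed called with an estimated correlation (adjusted p = 8.3e-04, 0.0128 and 0.00585).

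Among 11 MHC class II genes 2 rose and 1 fell (2 and 2 adjusted over the list alone): CD74, the class II invariant chain, rose by 3.47 ± 0.11, the protease CTSS by 2.78 ± 0.12, and HLA-DMB fell by 1.82 ± 0.44 on the log2 scale, a call that ended without TNF library 1. The median of that list was 0.19, its mean -0.30 and its test upward (adjusted p = 5.6e-05, and adjusted p = 0.0243 with an estimated correlation). Of 13 leukocyte markers 3 rose (3 adjusted over the list alone), including ITGAM, an integrin chain, at 5.57 ± 0.19 and LAPTM5, a lysosomal membrane protein, at 3.74 ± 0.53, with adjusted p = 0.0011 for the list and adjusted p = 0.0428 with an estimated correlation. Other named rises were LTB, a TNF family cytokine, at 5.83 ± 0.32, the amino acid oxidase IL4I1 at 5.61 ± 0.28 and the ubiquitin-like UBD at 5.60 ± 0.24. Named falls were ADH6, an alcohol dehydrogenase, at -5.99 ± 0.49, the annexin ANXA13 at -5.85 ± 0.82 (0.106 and 0 CPM in the TNF libraries) and IQGAP2, a scaffold protein, at -3.10 ± 0.38 (2.50 CPM in TNF library 1 and 8.74 in library 3, against 46.8 to 49.6 in the controls). LST1 had 0 counts in the 3 control libraries and 0.727 ± 0.0572 CPM (SD, n = 2) with TNF, so no fold is given.

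Genes of cell death moved in several lists. Of 33 pro-apoptotic genes and caspases 11 rose and 22 were not called (14 rose and 1 fell adjusted over the list alone), including BMF at 1.27 ± 0.12, BID at 1.17 ± 0.12 and the death ligand TNFSF10 at 1.75 ± 0.18. Of 18 anti-apoptotic genes 6 rose and 1 fell (7 and 1 adjusted over the list alone). BIRC3, an inhibitor of apoptosis, rose by 3.39 ± 0.48, with 43.1 CPM in TNF library 1 and 243.4 in library 3. Of 21 necroptosis and pyroptosis genes 9 rose (10 rose and 1 fell adjusted over the list alone), with the nucleic acid sensor ZBP1 at 3.81 ± 0.42. CASP8 did not pass the test (log2 0.27, 95% interval 0.06 to 0.48, adjusted p = 0.078). The 3 lists were called upward (adjusted p = 2.6e-04, 0.001 and 0.0094), and each call was lost with an estimated correlation (adjusted p = 0.188, 0.0665 and 0.0665 with an estimated correlation).

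In ferroptosis genes TNF gave rises and falls. GPX4, the lipid peroxide reductase, rose by 0.49 ± 0.13 (adjusted p = 0.0242), and SLC7A11, the cystine importer, fell by 1.82 ± 0.36 on the log2 scale (adjusted p = 0.0062). The TNF libraries were far apart here: SLC7A11 lay at 37.4 CPM in library 1 and 108.6 in library 3, against 184 to 304.2 in the controls. GPX4 lay at 367 and 256.2 CPM against 217.2 to 225.2, and its call ended without TNF library 1 and without control library 1 or 3. The prostaglandin synthase PTGS2 rose by 0.95 ± 0.26, and that call ended without control library 1 or TNF library 3. ACSL4 stood at -0.67 ± 0.34 (adjusted p = 0.207), with 17.3 CPM in TNF library 1 and 58.8 in library 3 against 59.4 to 62.2 in the controls, and it was called lower without TNF library 3. CHAC1 stood at -0.51 ± 0.26 (adjusted p = 0.209). Of 30 ferroptosis suppressors 6 rose and 4 fell (8 and 6 adjusted over the list alone), and of 31 drivers and markers 5 rose and 1 fell (6 and 1 adjusted over the list alone). Neither list passed camera (adjusted p = 0.882 and 0.723).

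Lysosomal genes rose in 25 of 48 members (28 adjusted over the list alone), with CTSA at 0.78 ± 0.09 and GLA at 0.67 ± 0.09, and adjusted p = 0.109 with an estimated correlation. Cholesterol synthesis rose in 11 of 28 (17 adjusted over the list alone), with LSS at 0.84 ± 0.11 and SQLE at 0.70 ± 0.11, and adjusted p = 0.472 with an estimated correlation. ATF4 stress response genes fell in 9 of 42 members (9 adjusted over the list alone), with the tRNA ligase GARS1 at -1.03 ± 0.14, and adjusted p = 0.604 with an estimated correlation. Among 20 goblet and secretory markers 5 fell and 1 rose (5 and 2 adjusted over the list alone), AGR2 falling by 1.43 ± 0.15, with adjusted p = 0.408 with an estimated correlation. The pore-forming claudin CLDN2 fell by 2.56 ± 0.25 on the log2 scale. In all, 3255 genes were called at adjusted p below 0.05, 1827 higher and 1428 lower, and 1245 of them changed at least 2-fold. The call count was 397 when only control and TNF libraries were fitted and 1514 with limma voom and quality weights, and voom (655 higher and 859 lower) and DESeq2 (2368 and 2482) called more falls than rises. Leaving out control library 1 gave 1766 genes, control library 3 gave 2002 and TNF library 3 gave 7380 (3156 higher and 4224 lower).

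**Figure D2:**
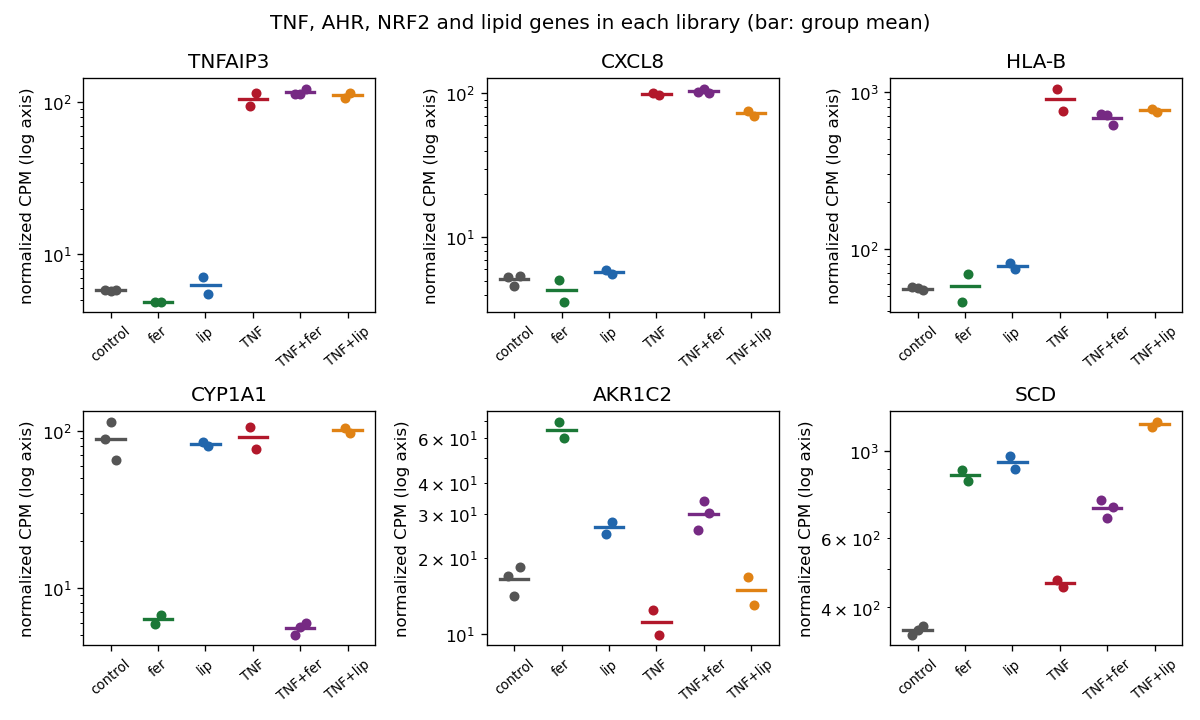
Normalized CPM on a log axis for 6 genes in each library, by group, with a bar at the group mean and fer and lip standing for ferrostatin-1 and liproxstatin-1. CYP1A1 averages 6.33 CPM with ferrostatin-1 and 5.58 CPM with TNF and ferrostatin-1, against 82.7 to 101 CPM in the other groups.

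Ferrostatin-1 alone lowered aryl hydrocarbon receptor (AHR) targets and raised NRF2, LXR and fatty acid genes. CYP1A1, an AHR-induced cytochrome P450 (ENSG00000140465, chromosome 15, 74719542 to 74725536, minus strand), fell from 89.6 ± 24.5 CPM (SD, n = 3) to 6.33 ± 0.548 CPM (SD, n = 2), a log2 change of -3.82 ± 0.24 (SE, adjusted p = 2.5e-05). CYP1B1 fell by 1.47 ± 0.16 and the aldehyde dehydrogenase ALDH1A3 by 1.36 ± 0.09 on the log2 scale, and 3 of 15 AHR targets fell (3 fell and 2 rose adjusted over the list alone). Of 43 NRF2 targets 10 rose and 33 were not called (22 rose and 1 fell adjusted over the list alone), with the aldo-keto reductases AKR1C2 at 1.97 ± 0.17, AKR1C1 at 1.83 ± 0.21 and AKR1B10 at 1.09 ± 0.13. The AKR1C genes are close copies, so their separate values are uncertain. SCD, the stearoyl-CoA desaturase (ENSG00000099194, chromosome 10, 100347233 to 100364826, plus strand), rose by 1.31 ± 0.07 (adjusted p = 1.1e-05) and the acyl-CoA synthetase ACSL1 by 0.78 ± 0.10, and 5 of 29 fatty acid synthesis genes rose (12 rose and 1 fell adjusted over the list alone). Of 12 LXR targets 6 rose (6 adjusted over the list alone), with the sterol exporters ABCA1 at 1.55 ± 0.27 and ABCG1 at 1.55 ± 0.24 and the ubiquitin ligase MYLIP at 0.85 ± 0.10.

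DNA replication genes fell in 16 of 41 members with ferrostatin-1 alone (38 adjusted over the list alone), with the ribonucleotide reductase subunit RRM2 at -0.92 ± 0.10, the helicase subunit MCM5 at -0.85 ± 0.13 and UHRF1 at -0.75 ± 0.11. The matrix protein TNC rose by 2.54 ± 0.32, CEACAM5 by 1.55 ± 0.18 and KRT20 by 0.97 ± 0.14, and CLDN2 fell by 1.79 ± 0.24 on the log2 scale. GPX4 stood at -0.01 (95% interval -0.29 to 0.26), SLC7A11 at 0.47 (-0.25 to 1.19) and AIFM2 at 0.49 (0.19 to 0.79, adjusted p = 0.152), and 1 of 30 ferroptosis suppressors rose (8 rose and 1 fell adjusted over the list alone). The NRF2, AHR, fatty acid, LXR, replication and suppressor lists were called (adjusted p = 3.6e-30, 1.0e-06, 1.0e-11, 4.7e-17, 4.2e-49 and 4.6e-05), and stayed called with an estimated correlation (adjusted p = 0.018, 0.0075, 0.0069, 8.1e-04, 0.0243 and 0.0344). The interferon list had 0 called members, a median of 0.19, a mean of -0.02 and an upward test (adjusted p = 0.0167, and adjusted p = 0.804 with an estimated correlation). KRT81 lay at 57.05 and 1.45 CPM in the ferrostatin-1 libraries, beside all of these groups. In total 125 genes were called, 41 higher and 84 lower, and 47 changed at least 2-fold. The count was 797 with DESeq2, 204 with the stricter filter, 441 with the length and GC offset, 1604 with voom, 36 with the marker covariate and 13 on these groups alone. Leaving out control library 1, 2 or 3 gave 26, 80 or 295 genes, and leaving out ferrostatin-1 library 1 or 3 gave 25 or 13. Of 30 called genes followed singly, 16, 25 or 29 kept the call without control library 1, 2 or 3, and 13 or 8 without ferrostatin-1 library 1 or 3.

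Liproxstatin-1 alone raised lipid genes and left CYP1A1 near its control level. SCD rose from 350 ± 8.90 CPM (SD, n = 3) to 933.7 ± 47.3 CPM (SD, n = 2), a log2 change of 1.42 ± 0.07 (adjusted p = 4.3e-06). ACSL1 rose by 1.06 ± 0.10, while CYP1A1 stood at -0.12 (95% interval -0.55 to 0.32). The amino acid transporter SLC6A20 rose by 1.33 ± 0.19, CEACAM5 by 1.32 ± 0.19, the transmembrane mucin MUC13 by 0.73 ± 0.09 and the mitochondrial lysine tRNA MT-TK by 2.98 ± 0.37. MT-TK is a short transcript in poly(A) libraries, so its level is uncertain.

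Of 29 fatty acid synthesis genes 2 rose with liproxstatin-1 alone (17 adjusted over the list alone), and of 12 LXR targets 1 rose (5 adjusted over the list alone). Among 18 absorptive enterocyte markers 1 rose (7 adjusted over the list alone), and among 30 ferroptosis suppressors 1 rose (5 adjusted over the list alone). These 4 lists stayed called with an estimated correlation (adjusted p = 0.0024, 0.0014, 0.0089 and 0.0293). The interferon list had 0 called members of 52 (31 rose adjusted over the list alone), a median of 0.70, and adjusted p = 0.0608 with an estimated correlation. Replication genes had 0 called members of 41 (27 fell adjusted over the list alone), with adjusted p = 0.104 with an estimated correlation, and AHR targets had 0 called of 15 (0 adjusted over the list alone). GPX4 stood at 0.08 (-0.20 to 0.35) and SLC7A11 at 0.40 (-0.32 to 1.12). KRT81 lay at 1.05 and 14 CPM in the liproxstatin-1 libraries, beside 47.6 to 48.4 in the controls. In total 13 genes were called, 12 higher and 1 lower, and 9 changed at least 2-fold. The count was 478 with DESeq2 (225 higher and 253 lower), 25 with the stricter filter, 77 with the length and GC offset, 1463 with voom, 2 with the marker covariate and 3 on these groups alone. Leaving out control library 1, 2 or 3 gave 3, 7 or 52 genes, and leaving out liproxstatin-1 library 1 or 3 gave 1 or 9, the 9 being 3 higher and 6 lower. Of 9 called genes followed singly, 2, 4 or 9 kept the call without control library 1, 2 or 3, and 1 or 3 without liproxstatin-1 library 1 or 3.

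Compared directly without TNF, the compounds differed at AHR targets. CYP1A1 was higher with liproxstatin-1 than with ferrostatin-1 by log2 3.71 ± 0.25 (adjusted p = 9.6e-05), CYP1B1 by 1.63 ± 0.17 and ALDH1A3 by 1.26 ± 0.10, and 3 of 15 AHR targets were higher (4 adjusted over the list alone; adjusted p = 3.2e-13, and adjusted p = 0.0015 with an estimated correlation). SLC6A20 was higher by 1.85 ± 0.22, the NADPH oxidase NOX1 by 1.73 ± 0.26 and MUC13 by 1.14 ± 0.10, whereas the amino acid transporter SLC38A4 was lower at -2.73 ± 0.30 and AKR1C2 at -1.29 ± 0.19. Of 18 enterocyte markers 1 was higher (5 higher and 1 lower adjusted over the list alone), with adjusted p = 0.0328 with an estimated correlation. SCD did not pass the test of the difference (log2 0.11, 95% interval -0.06 to 0.28, adjusted p = 0.976), nor did GPX4 (0.09, -0.21 to 0.39). KRT81 lay at 57.05 and 1.45 CPM in the ferrostatin-1 libraries and at 1.05 and 14 CPM in the liproxstatin-1 libraries. In total 23 genes were called, 19 higher with liproxstatin-1 and 4 lower. The count was 211 with DESeq2, 93 on these groups alone, 72 with the length and GC offset, 302 with voom and 8 with the marker covariate. Leaving out ferrostatin-1 library 1 gave 7 genes, liproxstatin-1 library 1 gave 3 and liproxstatin-1 library 3 gave 12. Of 12 called genes followed singly, 5 or 7 kept the call without ferrostatin-1 library 1 or 3, and 3 or 6 without liproxstatin-1 library 1 or 3.

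Added to TNF, ferrostatin-1 again went with lower AHR targets and with lower ATF4 genes. CYP1A1 fell by 4.03 ± 0.21 on the log2 scale (adjusted p = 3.5e-06), ALDH1A3 by 1.76 ± 0.09 and CYP1B1 by 1.24 ± 0.15, and 3 of 15 AHR targets fell (4 fell and 1 rose adjusted over the list alone; adjusted p = 1.7e-07, and adjusted p = 0.0137 with an estimated correlation). CHAC1, a glutathione-degrading enzyme (ENSG00000128965, chromosome 15, 40952962 to 40956512, plus strand), fell from 53.9 ± 20.2 CPM (SD, n = 2) to 16.7 ± 1.93 CPM (SD, n = 3), a log2 change of -1.69 ± 0.25 (adjusted p = 0.0089). DDIT3 fell by 1.76 ± 0.27 and the transcription factor ATF4 by 1.14 ± 0.18 on the log2 scale, and 12 of 42 ATF4 response genes fell (16 fell and 1 rose adjusted over the list alone), with adjusted p = 0.536 with an estimated correlation. TNF library 1 stood apart from library 3, and CHAC1 lay at 68.2 CPM in library 1 and 39.6 CPM in library 3. Of 48 lysosomal genes 16 fell (29 adjusted over the list alone), with FUCA1 at -0.81 ± 0.10 and NEU1 at -0.72 ± 0.11, and adjusted p = 0.309 with an estimated correlation. NRF2 targets had 8 rises and 1 fall among 43 (12 and 2 adjusted over the list alone), with AKR1C2 at 1.42 ± 0.18 and AKR1B10 at 1.20 ± 0.14. That list had a median of -0.01, a mean of 0.15 and an upward test, with adjusted p = 0.636 with an estimated correlation.

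LXR targets rose in 3 of 12 members when ferrostatin-1 was added to TNF (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.353 with an estimated correlation), with ABCA1 at 2.37 ± 0.30 (2.14 and 4.90 CPM in TNF libraries 1 and 3, 16.8 to 19.7 with ferrostatin-1), and 6 of 29 fatty acid genes rose (7 adjusted over the list alone; adjusted p = 0.396 with an estimated correlation), with SCD at 0.63 ± 0.07. GPX4 fell by 0.58 ± 0.13 on the log2 scale (adjusted p = 0.0303), from 367 and 256.2 CPM in TNF libraries 1 and 3 to 194.7 to 217.7, and the call ended without TNF library 1 and without any library with ferrostatin-1. SLC7A11 stood at 0.80 ± 0.34 (adjusted p = 0.152), with 37.4 and 108.6 CPM in TNF libraries 1 and 3 and 109.6 to 138.5 with ferrostatin-1. TNFAIP3 stood at 0.15 (95% interval -0.11 to 0.40) and CXCL8 at 0.06 (-0.22 to 0.34), whereas 5 of 49 NF-kB targets fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). CD74 fell by 0.72 ± 0.11, BMF by 0.91 ± 0.12 and the immediate early gene FOS by 1.27 ± 0.13 on the log2 scale. The 220 genes that rose at least 2-fold had a median transcript length of 6117 bases, against 2756 for all tested genes, and among them were BIRC6 at 1.86 ± 0.35, RANBP2 at 1.89 ± 0.41 and CRYBG3 at 2.02 ± 0.43. BIRC6 (ENSG00000115760, chromosome 2, 32357028 to 32618899, plus strand) lay at 22.5 and 66.7 CPM in the TNF libraries and at 143 to 187 CPM with ferrostatin-1. RANBP2 lay at 14.3 and 55.6 CPM in TNF libraries 1 and 3 and at 111.1 to 153.2 with ferrostatin-1, and CRYBG3 at 4.63 and 21.05 and at 45.25 to 57.4, so these folds differ by TNF library. The RANBP2 and CRYBG3 calls ended without any 1 library with ferrostatin-1, and the BIRC6 call without library 2 or 3.

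Falls with ferrostatin-1 under TNF included genes of the set led by KRT81, which were high in both TNF libraries and low in all 3 libraries with ferrostatin-1. KRT81 averaged 47.1 ± 4.73 CPM (SD, n = 2) with TNF and 1.67 ± 0.170 CPM (SD, n = 3) with ferrostatin-1 added, RFLNA 3.46 and 0.0479 CPM, and COL6A2 9.11 and 0.191 CPM. CXCL5 and ADAMTS12 had 0 counts in all 3 libraries with ferrostatin-1 and 5.61 ± 1.68 and 1.29 ± 0.325 CPM (SD, n = 2) with TNF, so no fold is given. BEST1 averaged 384 ± 166 CPM with TNF and 3.81 ± 2.51 CPM with ferrostatin-1 added. BEST1 also differed within groups, at 291.6 and 7.655 CPM in ferrostatin-1 libraries 1 and 3. With TNF and liproxstatin-1 it lay at 10.05 and 274.4 CPM in libraries 1 and 2, where KRT81 lay at 13.55 and 1.85. The 4744 bp overlap of BEST1 with FTH1 on the opposite strand makes its values uncertain. These 6 calls ended without any 1 library with TNF and ferrostatin-1, and those of KRT81, COL6A2 and CXCL5 also without TNF library 1. Of 13 fibroblast markers 3 fell (6 adjusted over the list alone; adjusted p = 0.396 with an estimated correlation), with a fitted median of -3.74, or -2.81 with 5 members at 0 set to 3 counts over the group. In TNF against control 2 of the 13 rose (2 adjusted over the list alone), with a median of 1.54 and adjusted p = 0.0625, or adjusted p = 0.714 with an estimated correlation.

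With ferrostatin-1 added to TNF 1224 genes were called, 392 higher and 832 lower, of which 220 rose and 122 fell at least 2-fold. The count was 3828 with DESeq2 (1913 higher and 1915 lower), 537 with no filter, 2128 with the length and GC offset, 14 with voom, 7 with the marker covariate and 11 on these groups alone. Leaving out TNF library 1 gave 589 genes, 365 higher and 224 lower, and leaving out library 3 gave 7373, 4021 higher and 3352 lower, so the balance of rises and falls depended on that choice. Leaving out ferrostatin-1 library 1, 2 or 3 under TNF gave 191, 69 or 103. Of 34 called genes followed singly, 29 or 34 kept the call without TNF library 1 or 3, and 21, 18 or 18 without ferrostatin-1 library 1, 2 or 3 under TNF.

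**Figure D3:**
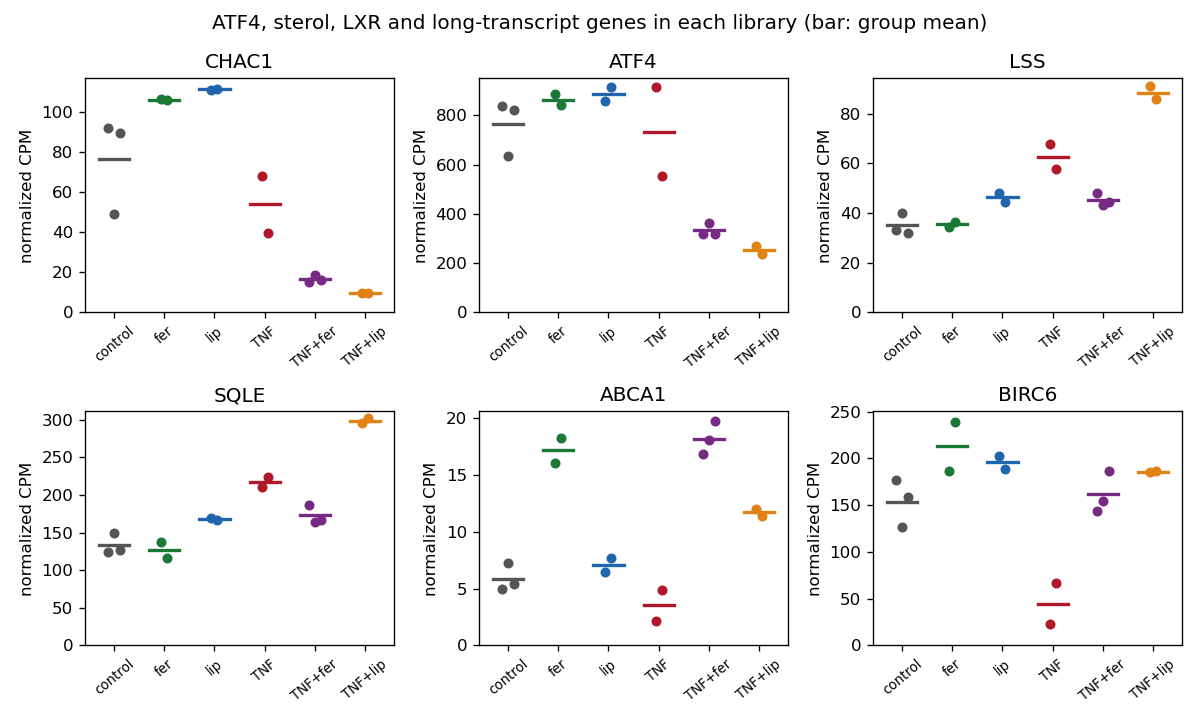
Normalized CPM in each library for CHAC1, ATF4, LSS, SQLE, ABCA1 and BIRC6, by group, with a bar at the group mean and each axis starting at 0. CHAC1 averages 53.9 CPM with TNF, 16.7 CPM with TNF and ferrostatin-1 and 9.68 CPM with TNF and liproxstatin-1.

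Added to TNF, liproxstatin-1 went with lower ATF4 genes and higher lipid synthesis genes. CHAC1 fell by 2.48 ± 0.30 on the log2 scale (adjusted p = 0.0076), ATF4 by 1.53 ± 0.20 and TXNIP, a thioredoxin inhibitor, by 2.19 ± 0.24. Of 42 ATF4 response genes 6 fell (25 adjusted over the list alone; adjusted p = 1.8e-19, and adjusted p = 0.362 with an estimated correlation). Those genes were higher in TNF library 1 than in library 3 by a median log2 of 0.56. SCD rose by 1.34 ± 0.08 (adjusted p = 3.3e-05), ACSL1 by 1.19 ± 0.11 and the fatty acid synthase FASN by 1.03 ± 0.15, and 5 of 29 fatty acid genes rose (9 rose and 1 fell adjusted over the list alone; adjusted p = 0.0582 with an estimated correlation). HMGCS1, of the sterol pathway, rose by 1.37 ± 0.23, and 2 of 28 cholesterol synthesis genes rose (13 adjusted over the list alone; adjusted p = 0.362 with an estimated correlation). ABCA1 rose by 1.73 ± 0.31 (2.14 and 4.90 CPM in TNF libraries 1 and 3, 11.97 and 11.4 with liproxstatin-1), with 2 of 12 LXR targets called (4 adjusted over the list alone; adjusted p = 0.0582 with an estimated correlation). MUC13 rose by 0.92 ± 0.10, the proliferation marker MKI67 by 1.46 ± 0.14 and BIRC6 by 2.06 ± 0.37, and FOS fell by 1.10 ± 0.14 on the log2 scale. MKI67 lay at 162.8 and 184.1 CPM in TNF, 311.3 to 375.7 in the controls and 469 and 482 with liproxstatin-1 under TNF. RRM2 lay at 194.7 and 189.6 CPM in TNF and 225.1 and 234.2 with liproxstatin-1 added. CDC45 lay at 74.52 and 75.56, and at 73.67 and 73.25. The MKI67 rise thus does not show higher proliferation. BIRC6 lay at 22.5 and 66.7 CPM in TNF libraries 1 and 3 and at 185.1 and 186.1 with liproxstatin-1, so its fold differs by TNF library. The calls of CHAC1, ATF4, TXNIP, FASN, HMGCS1, ABCA1, BIRC6 and FOS ended without either library with TNF and liproxstatin-1.

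With liproxstatin-1 under TNF, CYP1A1 stood at 0.15 (95% interval -0.33 to 0.63), TNFAIP3 at 0.08 (-0.20 to 0.36) and GPX4 at -0.37 (-0.67 to -0.06, adjusted p = 0.154). CASP8 stood at -0.31 (-0.54 to -0.08, adjusted p = 0.126), and 0 of 33 pro-apoptotic genes were called (5 fell adjusted over the list alone; adjusted p = 0.362 with an estimated correlation). NF-kB targets had 0 called of 49 (5 fell adjusted over the list alone; adjusted p = 0.364 with an estimated correlation). KRT81 averaged 47.1 CPM with TNF and 7.70 ± 8.27 CPM (SD, n = 2) with liproxstatin-1 added. In total 76 genes were called, 53 higher and 23 lower, and 53 changed at least 2-fold. The count was 2429 with DESeq2 (1142 higher and 1287 lower), 117 with the stricter filter, 1283 with the length and GC offset (567 higher and 716 lower), 123 with voom, 3 with the marker covariate and 0 on these groups alone. At an unadjusted p below 0.05, edgeR passed 5119 genes in the fit of all groups. Leaving out TNF library 1 or 3 gave 356 or 6797 genes, and leaving out liproxstatin-1 library 1 or 2 under TNF gave 6 or 4. Of 22 called genes followed singly, 20 or 22 kept the call without TNF library 1 or 3, but 3 or 4 without liproxstatin-1 library 1 or 2 under TNF.

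Compared directly under TNF, AHR target, cholesterol synthesis, enterocyte and goblet marker genes were higher with liproxstatin-1 than with ferrostatin-1 at the same 20 uM and 72 h. CYP1A1 averaged 91.0 CPM with TNF alone, 101 with liproxstatin-1 added and 5.58 with ferrostatin-1 added, so its difference lay in the ferrostatin-1 group. Against TNF alone, the goblet list had a median log2 of 0.047 with liproxstatin-1 and -0.25 with ferrostatin-1. CYP1A1 was higher by log2 4.18 ± 0.21 (adjusted p = 2.4e-06), ALDH1A3 by 1.80 ± 0.09 and CYP1B1 by 1.49 ± 0.15, and 3 of 15 AHR targets were higher (4 higher and 1 lower adjusted over the list alone). Of 28 cholesterol synthesis genes 8 were higher and 0 lower (22 adjusted over the list alone), with LSS, the lanosterol synthase (ENSG00000160285, chromosome 21, 46188141 to 46228822, minus strand), at 0.97 ± 0.11, DHCR7 at 0.81 ± 0.11 and SQLE at 0.79 ± 0.11. FASN was higher by 0.97 ± 0.13, ACSL1 by 0.72 ± 0.10 and SCD by 0.71 ± 0.07. SLC6A20 was higher by 3.36 ± 0.20, MUC13 by 1.26 ± 0.09 and CEACAM7 by 1.95 ± 0.34, and 3 of 18 enterocyte and 3 of 20 goblet markers were higher (8 and 8 adjusted over the list alone). Of 48 lysosomal genes 4 were higher (19 adjusted over the list alone), with NEU1 at 0.87 ± 0.11 and FLCN at 0.73 ± 0.11. The AHR, cholesterol, enterocyte, goblet and lysosome lists stayed called with an estimated correlation (adjusted p = 0.0012, 0.0244, 0.0244, 0.0244 and 0.0437).

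Lower with liproxstatin-1 than with ferrostatin-1 under TNF were SOD2, the mitochondrial superoxide dismutase, at -0.58 ± 0.08, the metallothionein MT2A at -1.08 ± 0.18, PDK4 at -1.61 ± 0.28 and AKR1B10 at -0.94 ± 0.13. Of 43 NRF2 targets 2 were lower (9 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation), and 2 of 12 metallothionein and zinc transport genes were lower (2 adjusted over the list alone; adjusted p = 0.0595 with an estimated correlation). Metallothioneins are close copies, so their separate values are uncertain. ATF4 response genes had 0 called of 42 (0 adjusted over the list alone), with adjusted p = 0.435 with an estimated correlation. NF-kB targets had a median of -0.06, a mean of 0.03 and a downward test (adjusted p = 0.024, and adjusted p = 0.555 with an estimated correlation). GPX4 did not pass the test (log2 0.21, 95% interval -0.06 to 0.49). KRT81 lay at 13.55 and 1.85 CPM with liproxstatin-1 and at 1.47 to 1.80 CPM with ferrostatin-1. In total 170 genes were called, 151 higher and 19 lower, and 71 changed at least 2-fold. The count was 467 with DESeq2, 105 with no filter, 106 with the marker covariate, 813 with voom and 575 on these groups alone. Leaving out ferrostatin-1 library 1, 2 or 3 gave 65, 46 or 52 genes, and leaving out liproxstatin-1 library 1 or 2 gave 26 or 31. Of 27 called genes followed singly, 18, 16 or 17 kept the call without ferrostatin-1 library 1, 2 or 3, and 8 or 10 without liproxstatin-1 library 1 or 2.

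**Figure D4:**
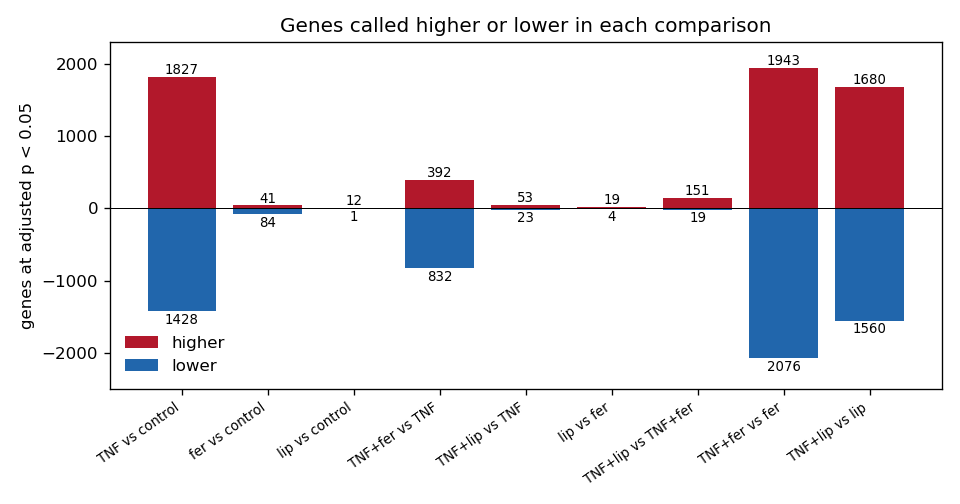
Number of genes called higher (above 0) and lower (below 0) at adjusted p below 0.05 in 9 comparisons, with fer and lip standing for ferrostatin-1 and liproxstatin-1. The bars run from 12 higher and 1 lower with liproxstatin-1 alone to 1943 higher and 2076 lower for TNF in cells with ferrostatin-1.

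TNF raised NF-kB targets in cells kept with either compound. TNFAIP3 rose by 4.58 ± 0.15 with ferrostatin-1 and 4.14 ± 0.15 with liproxstatin-1, CXCL8 by 4.58 ± 0.16 and 3.67 ± 0.16, HLA-B by 3.57 ± 0.19 and 3.30 ± 0.20, and CD74 by 3.00 ± 0.13 and 3.23 ± 0.13. Of 49 NF-kB targets 33 rose and 3 fell with ferrostatin-1 (33 and 5 adjusted over the list alone), and 29 rose and 1 fell with liproxstatin-1 (33 and 2). Of 52 interferon genes 40 and 24 rose (47 and 30 adjusted over the list alone), with adjusted p = 0.0498 and 0.143 with an estimated correlation. SLC7A11 fell by 1.49 ± 0.33 with ferrostatin-1 and by 1.81 ± 0.38 with liproxstatin-1 on the log2 scale, and these calls ended without ferrostatin-1 library 3 and without either library with TNF and liproxstatin-1. ATF4 response genes fell in 35 and 37 of 42 members (38 and 37 fell and 1 and 1 rose adjusted over the list alone), with adjusted p = 0.0607 and 0.0546 with an estimated correlation. Replication genes rose in 38 and 29 of 41 members (39 and 38 adjusted over the list alone), with adjusted p = 0.0498 and 0.103 with an estimated correlation. RRM2 lay at 151.1 to 193.4 CPM in the controls and at 194.7 and 189.6 with TNF alone. With ferrostatin-1 RRM2 lay at 95.22 and 86.68 without TNF and at 184.8 to 192.4 with it. With liproxstatin-1 RRM2 lay at 132.9 and 130.4 without TNF and at 225.1 and 234.2 with it. For RRM2 both rises thus started below the control range, and that with ferrostatin-1 ended within it.

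With ferrostatin-1 present TNF changed 4019 genes, 1943 higher and 2076 lower, and 1409 at least 2-fold. With liproxstatin-1 it changed 3240, 1680 higher and 1560 lower, and 1270 at least 2-fold. KRT81 averaged 29.3 and 1.67 CPM in the ferrostatin-1 groups without and with TNF, and 7.52 and 7.70 CPM in the liproxstatin-1 groups. The ferrostatin-1 count was 6937 on these groups alone, 2502 with the marker covariate and 7240 with voom, and 1877 or 1919 without ferrostatin-1 library 1 or 3. The liproxstatin-1 count was 5943 on these groups alone and 6848 with voom, 1361 or 1430 without liproxstatin-1 library 1 or 3, and 1485 or 1328 without liproxstatin-1 library 1 or 2 under TNF.

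Effects of TNF correlated across genes, which are not independent replicates, with r = 0.381 between cells kept with ferrostatin-1 and with liproxstatin-1, which share no library. Among called genes 1203 rose in both and 1268 fell in both, against 147.2 and 146 for independent lists, and 4 went opposite ways. The values for independent lists here and below treat every tested gene as equally likely to be called. Genes with high counts or a low spread are called more readily in any comparison, so these values are likely too low. The effect of TNF without compound correlated at r = 0.276 with that under ferrostatin-1 and 0.232 with that under liproxstatin-1. Of the 610 genes raised at least 2-fold by TNF alone, 435 rose with ferrostatin-1 and 403 with liproxstatin-1, and of the 635 lowered, 183 and 125 fell. Median log2 changes of the raised genes were 1.65, 1.33 and 1.24, and of the lowered genes -1.40, -0.545 and -0.344. The 2-fold choice was made in the TNF libraries, of which library 1 stood apart, and favours larger changes there. These counts therefore do not show that a compound prevented falls. The difference between compounds without TNF and under TNF correlated at r = 0.0757, with 16 genes higher and 1 lower in both and 0 opposite, against 0.129 and 0.0034 for independent lists. Over genes with a mean CPM of at least 10 these correlations were 0.909, 0.564, 0.507 and, for the compound difference, 0.470. Ferrostatin-1 effects without and with TNF correlated at 0.0273 and liproxstatin-1 effects at 0.0241 (0.121 and -0.0416 at a mean CPM of at least 10). Among called genes 16 rose and 17 fell with ferrostatin-1 both without and with TNF and 2 went opposite ways, against 0.725, 3.15 and 3.02 for independent lists. With liproxstatin-1 6 rose in both and 0 went opposite ways, against 0.0287 and 0.0148. Ferrostatin-1 and liproxstatin-1 alone share the control libraries, and their effects correlated at 0.392 against 0.383 between simulated unchanged groups, with a covariance of 0.458 against 0.297. Under TNF the compounds share the TNF libraries, with 0.638 against 0.543 simulated and a covariance of 0.882 against 0.457. Of called genes 37 rose and 16 fell with both compounds under TNF, and 4 rose and 1 fell with both alone, against 0.937, 0.863, 0.0222 and 0.0038 for independent lists. Splitting the shared groups would leave fewer than 2 libraries on a side, so part of these excesses may come from the shared libraries.

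These correlations moved when 1 library was left out. That between TNF effects within the compounds was 0.232 without library 2 with TNF and liproxstatin-1. Those of TNF without compound were lowest at 0.140 (ferrostatin-1, without ferrostatin-1 library 3) and 0.110 (liproxstatin-1, without TNF library 3). The compound difference gave 0.0199 without liproxstatin-1 library 3. Ferrostatin-1 effects without and with TNF gave -0.0534 without ferrostatin-1 library 3 and 0.0641 without library 1, and liproxstatin-1 effects -0.0349 without TNF library 1 and 0.0731 without library 2 with TNF and liproxstatin-1, so the sign of these 2 correlations over all genes changed with the library left out.

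The interaction tests asked whether a compound acted differently with TNF than without it. In simulated counts they recovered 5.97%, 7.46% and 8.96% of genes changed 2-fold, so few calls say little about changes of that size. WDR76, a DNA damage-associated WD40 protein (ENSG00000092470, chromosome 15, 43826980 to 43867018, plus strand), was the 1 gene called for ferrostatin-1, at 1.62 ± 0.18 (adjusted p = 0.0303). WDR76 averaged 26.8 ± 3.02 CPM in controls (SD, n = 3), 12.4 ± 1.23 with ferrostatin-1 (n = 2), 24.5 ± 2.90 with TNF (n = 2) and 34.96 ± 0.422 with both (n = 3). CHAC1 did not pass, at -2.16 ± 0.36 for ferrostatin-1 (adjusted p = 0.0544) and -3.01 ± 0.38 for liproxstatin-1 (adjusted p = 0.0519). CYP1A1 stood at -0.20 (95% interval -0.83 to 0.43) for ferrostatin-1, 0.27 (-0.38 to 0.91) for liproxstatin-1 and 0.47 (-0.19 to 1.13) for the difference between compounds. With edgeR 0 genes were called for liproxstatin-1 and 0 for the difference between compounds, where 4329 and 879 had an unadjusted p below 0.05 and DESeq2 called 1267 and 19. For ferrostatin-1 4238 genes had an unadjusted p below 0.05, DESeq2 called 1331, and relative log expression scaling gave 17 genes, 6 higher and 11 lower, in place of 1 higher and 0 lower. Without TNF library 3 the counts were 6147 for each compound, and without TNF library 1 they were 217 and 239. For ferrostatin-1 the count was 0, 38 or 27 without control library 1, 2 or 3, 7 without ferrostatin-1 library 3, and 0 without library 1 or 3 with TNF and ferrostatin-1. For liproxstatin-1 it was 18 without control library 2, 2 without liproxstatin-1 library 3 and 1 without liproxstatin-1 library 1 under TNF, and for the difference between compounds it ran from 0 to 3. The WDR76 call ended on these groups alone, with the marker covariate, and without control library 1, ferrostatin-1 library 1 or any library with TNF and ferrostatin-1.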

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

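The tests of transcript length, of liproxstatin-1 alone on the ATF4 list, of the fibroblast list and of the falls without TNF library 1 were chosen after the results were seen, as were the marker covariate, the length and GC offset and the fits without TNF library 1 of gene lists.

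WDR76 drew attention because ferrostatin-1 changed it differently with TNF than without, by log2 1.62. Of the camera tests of lists for the 3 interactions 50 were called (16, 19 and 15, with lists counted in each), and 0 of these stayed called with an estimated correlation. For ferrostatin-1 by TNF the medians were 0.90 for S phase and DNA replication, 0.94 for G2M and mitosis, -0.85 for the ATF4 response, -0.65 for immediate early genes, -0.38 for ribosomal proteins, -0.37 for MHC class I, -0.36 for LXR targets, -0.33 for epithelial-mesenchymal transition and -0.31 for NRF2 targets. The same interaction gave -0.26 for pro-apoptotic genes, -0.24 for lysosome, -0.22 for unfolded protein chaperones, -0.20 for goblet markers (mean 0.04), -0.19 for interferon-stimulated genes, -0.10 for ferroptosis suppressors and -4.48 for fibroblast markers, with adjusted p from 0.236 to 0.625 with an estimated correlation. With genes at 0 set to their floor, the fibroblast median was -3.24 and the LXR median -0.41.

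For liproxstatin-1 by TNF the medians were 0.63 for S phase and DNA replication, 0.83 for G2M and mitosis, -1.17 for the ATF4 response, -0.81 for immediate early genes, -0.70 for interferon-stimulated genes, -0.54 for MHC class I, -0.50 for epithelial-mesenchymal transition, -0.44 for ribosomal proteins, -0.43 for NF-kB targets and -0.38 for NRF2 targets. The other called lists lay at -0.34 for pro-apoptotic genes, -0.26 for necroptosis, -0.23 for ferroptosis suppressors, -0.22 for oxidative phosphorylation, -0.21 for lysosome, -0.18 for unfolded protein chaperones, -0.18 for p53 targets, -0.15 for hypoxia and -0.15 for autophagy, with adjusted p from 0.165 to 0.711 with an estimated correlation. With genes at 0 set to their floor, the immediate early median was -0.66.

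For the difference between compounds by TNF the medians were -0.41 for interferon-stimulated genes, -0.32 for the ATF4 response, -0.28 for S phase, -0.21 for MHC class I, -0.16 for ribosome biogenesis, -0.15 for hypoxia, -0.14 for NRF2 targets, -0.12 for NF-kB targets (mean 0.45), -0.10 for anti-apoptotic genes and -0.072 for oxidative phosphorylation. Upward lists were cholesterol synthesis at 0.22, fatty acid synthesis at 0.14, LXR targets at 0.32, goblet markers at 0.41 and fibroblast markers at 3.47, or 2.84 with genes at 0 set to their floor. Adjusted p ran from 0.394 to 0.793 with an estimated correlation.

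With ferrostatin-1 added to TNF, 115 genes other than the markers fell at least 2-fold (median log2 -1.29), and RNA of other cells in some libraries was weighed against an effect of ferrostatin-1 on cells with TNF. KRT81 lay at 57.05 and 1.45 CPM in ferrostatin-1 libraries 1 and 3. Of the 115 genes, 13.0% were at least 2-fold higher in library 1, against 6.50% of all tested genes. All 115 were called in the model of all groups, which share their estimate of the spread. Genes that differ between these 2 libraries are less readily called there, and the markers were set aside. That share therefore cannot decide whether RNA of other cells caused most of these falls. With liproxstatin-1 added to TNF the same genes had a median of -0.52, and KRT81 was also low there, at 13.55 and 1.85 CPM. That value may go with RNA of other cells or with the TNF libraries that both comparisons share. TNF library 1 standing apart as the whole cause is argued against, for these genes, by a median of -1.17 without it. The genes were chosen in the fit with both TNF libraries, which favours genes alike in both, so that argument is weak. An effect of ferrostatin-1 may remain, with a median of -1.24 with the marker covariate. The slope of that covariate rests on score differences within groups, which were largest between ferrostatin-1 libraries 1 and 3 (1.23 and -1.01). It is thus not separate from the test on those 2 libraries. With the covariate 7 of the 115 genes were still called. The score nearly follows the 2 groups compared here, and the median SE rose from 0.258 to 0.410. For the 13 fibroblast markers the median log2 of ferrostatin-1 library 1 over library 3 was 0.74, between the bounds set for and against RNA of other cells. Some members also varied between libraries of 1 treatment. COL1A2 lay at 2.60, 0.491 and 0 CPM in the controls and at 0 and 1.81 with liproxstatin-1, whereas ACTA2 lay at 1.10, 1.67 and 0.891 in the controls. That variation did not follow treatment, but those explanations cannot be told apart for the whole list.

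With ferrostatin-1 added to TNF, 220 genes rose at least 2-fold (median log2 1.42). Without TNF library 1 the median was 0.90 and 131 of the genes were still called, so part of the size may come from that library. A transcript length bias in TNF library 1 also stays open: the log2 ratio of TNF library 1 to library 3 fell with transcript length (Spearman rho -0.184 across genes, against -0.129 to 0.0729 within other groups), and 191 genes were still called at a median of 0.97 with the length and GC offset. That ratio cannot show a bias common to both TNF libraries. BIRC6 lay at 22.5 and 66.7 CPM in the TNF libraries, 126.2 to 176.8 in the controls and 185.1 and 186.1 with TNF and liproxstatin-1. RANBP2 lay at 14.3 and 55.6, 120.4 to 166.4, and 162.8 and 163.2 CPM in the same groups. For these 2 genes the TNF group was low against controls and either compound. An effect of ferrostatin-1 present also without TNF stays open, at a median of 0.16 for the same genes with ferrostatin-1 alone. These explanations cannot be told apart with 2 TNF libraries.

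The ATF4 list was lower with liproxstatin-1 under TNF (42 genes, median log2 -0.73). An effect of liproxstatin-1 seen alike with and without TNF is argued against by a median of 0.41 with liproxstatin-1 alone. Control library 2 may enlarge that median. CHAC1 lay at 48.9 CPM there against 91.85 and 89.4 in control libraries 1 and 3, though PSPH lay at 97.2 against 97.6 and 94.1. With liproxstatin-1 alone CHAC1 lay at 110.9 and 111.6 CPM, above every control. Without TNF library 1 the median was -0.49 (SD 0.549 across genes), between the bounds set for and against that library as the cause, so it may account for part of the difference. An effect of liproxstatin-1 that needs TNF stays open and untested in further libraries.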

How the results depend on the processing

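The marker covariate, the length and GC offset, voom with quality weights, the block over labelled libraries, gene lists without TNF library 1 and the agreement of compound differences and of TNF effects within compounds were chosen after the data were seen. Where a library was left out and 1 remained in its group, that library was assumed to vary like the other groups. Causes were not tested, except that fits of fewer groups or libraries have fewer degrees of freedom. Alternatives for FPKM were not run because counts were used, and the strict filter left 492 of 504 list tests. No scaling shifted the median of all genes by more than 0.1. Over named genes and settings, 3216 values kept direction and call or lack of a call, 606 lost the call, 55 gained it, 26 changed sign without a call, and 3 reversed: HMGCS1 for TNF (0.51 without TNF library 1 and -0.42 without TNF library 3), KRT81 for ferrostatin-1 under TNF with the marker covariate (0.50), and SOD2 there with the length and GC offset (-0.65). Named genes called for ferrostatin-1 under TNF numbered 34, of which 6 kept the call with only the compared groups and 2 with the marker covariate. For liproxstatin-1 under TNF 0 and 2 of 22 kept it, for ferrostatin-1 alone 8 and 19 of 30, and for liproxstatin-1 alone 2 and 2 of 9. No alternative tested depth.

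Counts of called genes for TNF against control were 397 with only the compared groups, 1245 at the 2-fold threshold, 1514 with voom and 1766 to 7380 with a library left out. Ferrostatin-1 against control gave 204 with the strict filter, 797 with DESeq2, 13 with only the compared groups, 47 at 2-fold, 36 with the marker covariate, 441 with the length and GC offset, 1604 with voom and 13 to 295 with a library left out. Liproxstatin-1 against control gave 25, 478, 3, 2, 77 and 1463 with the strict filter, DESeq2, only the compared groups, the marker covariate, the offset and voom, and 1 to 52 with a library left out. Ferrostatin-1 under TNF gave 537 with no filter, 3828 with DESeq2, 11 with only the compared groups, 342 at 2-fold, 7 with the marker covariate, 2128 with the offset, 14 with voom and 69 to 7373 with a library left out. Liproxstatin-1 under TNF gave 117 with the strict filter, 2429 with DESeq2, 0 with only the compared groups, 3 with the marker covariate, 1283 with the offset, 123 with voom and 4 to 6797 with a library left out; edgeR's unadjusted p was below 0.05 for 5119 genes in the model of all groups.

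Between compounds without TNF the counts were 211 with DESeq2, 93 with only the compared groups, 8 with the marker covariate, 72 with the offset, 302 with voom and 3 to 17 with a library left out. Between compounds under TNF they were 105 with no filter, 467 with DESeq2, 575 with only the compared groups, 71 at 2-fold, 106 with the marker covariate, 813 with voom and 26 to 65 with a library left out. TNF with ferrostatin-1 gave 6937 with only the compared groups, 1409 at 2-fold, 2502 with the marker covariate, 7240 with voom and 1877 to 2870 with a library left out, and TNF with liproxstatin-1 gave 5943, 1270 and 6848 with only the compared groups, 2-fold and voom and 1328 to 1485 with a library left out. The ferrostatin-1 interaction gave 17 with relative log expression scaling, 37 with the strict filter, 1331 with DESeq2, 0 with only the compared groups, 0 with the marker covariate, 329 with the offset, 12 with voom and 0 to 6147 with a library left out. The liproxstatin-1 interaction gave 2 with no filter, 3 with the strict filter, 1267 with DESeq2, 1 with the marker covariate, 272 with the offset, 207 with voom and 0 to 6147 with a library left out. The difference between compounds by TNF gave 19 with DESeq2, 4 with only the compared groups, 8 with voom and 0 to 3 with a library left out.

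Of 504 list tests 211 were called at the preset correlation and 34 with an estimated one, and 132 of the 211 by fry. Over genes with a mean CPM of at least 10, correlations of effects were 0.564 for TNF without compound and with ferrostatin-1, 0.507 with liproxstatin-1, 0.909 for TNF within the compounds, 0.121 for ferrostatin-1 without and with TNF, -0.0416 for liproxstatin-1 without and with TNF, -0.0787 for liproxstatin-1 alone and ferrostatin-1 under TNF, 0.470 for the compound differences, 0.715 for the compounds alone and 0.873 for the compounds under TNF.

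Column numbers match the replicate numbers of the titles for the control and both combined treatment groups only, so the block used these 3 groups. Libraries with the same number did not deviate together (r = -0.0197, -0.132 and -0.120 for control with TNF and ferrostatin-1, -0.0131 and -0.0477 between the combined treatments, 0.216 and -0.216 for control with TNF and liproxstatin-1). With a replicate block on these libraries 81 genes differed between the compounds under TNF, against 256 in the same libraries without the block. The block called 23 lists against 20 in the same libraries without the block and 19 in the model of all libraries, and turned the direction of 0.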

Other observations

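The choice of the levels of HSPA6 was made after they were seen.

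Cells given TNF beside either compound differed from cells with the compound alone in several further groups. Of 31 immediate early genes 16 fell with ferrostatin-1 and 19 with liproxstatin-1 (21 fell and 1 rose, and 20 fell and 1 rose, adjusted over the list alone), with adjusted p = 0.135 and 0.11 with an estimated correlation. Of 44 mitotic genes 16 and 19 rose (25 and 30 adjusted over the list alone), with adjusted p = 0.252 and 0.186 with an estimated correlation. Ribosomal protein genes fell in 38 and 33 of 52 members (46 and 46 adjusted over the list alone), with adjusted p = 0.254 and 0.209 with an estimated correlation. Of 18 cytosolic heat shock genes 8 and 5 rose (10 and 6 adjusted over the list alone), with adjusted p = 0.15 and 0.214 with an estimated correlation.

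HSPA6, a stress-inducible heat shock protein of the HSP70 family, lay between 20.5 and 21.9 CPM in the controls, at 20.9 and 19.6 in TNF and at 22.35 in ferrostatin-1 library 1. In the other libraries HSPA6 lay between 0.455 and 2.01 CPM, including 1.37 in ferrostatin-1 library 3.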
